A study of Mus musculus with 12 samples.

How the data were processed

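RNA of C2C12 myoblasts was hybridised to 12 single-colour Affymetrix mouse arrays, 1 per culture. Cells had been infected with a retrovirus for Msx1-ER or with the empty vector and then treated with 0.2 nM tamoxifen or its solvent for 6 h, per the labels' protocols. Groups and replicate numbers came from the sample titles, with 3 arrays in each of 4 groups. The deposited values are log2 signals, 1 per probe set and array. The submitters' processing notes name MAS5 and limma, with no version. Turned back to the linear scale, each deposited array had a trimmed mean of 500 with 2% taken off each end, which is the global scaling that MAS5 applies. A probe set is a group of short probes for 1 transcript, and MAS5 summarises them without any step that makes the distributions of different arrays equal, so that dim probe sets vary widely on the log2 scale.

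The table held 12488 probe sets, of which 66 controls were left out. Of the other 12422, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 were not listed with a gene. Matching through Entrez identifiers to the RefSeq gene table found 10817 of these symbols and changed 0 of them. Probe sets in the lowest 40% by mean log2 signal over all arrays were left out, which kept 7453. Probe sets with several symbols or none were left out of the gene tests, and for the remaining genes the probe set with the highest mean stood for the gene. This gave 5624 genes, of which 1666 had more than 1 probe set on the array. No position of any probe was used. No further normalization was applied to the main values.

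All tests used R 4.3.3 and limma 3.58.1. A linear model with 4 group means was fitted to all 12 arrays, and variances were moderated with an intensity trend (8 residual and 7.11 prior degrees of freedom). Contrasts compared tamoxifen with solvent within each vector, the difference of these 2 responses, and Msx1-ER with empty vector with and without tamoxifen. P-values were 2-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. Errors of log2 changes are standard errors from the fit, and errors of group means are standard deviations over 3 arrays. Single-value checks of Msx1 used exact permutation tests.

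Before the data were examined, 33 gene lists were written, 28 of which had at least 5 measured members and were tested as sets with limma's camera, with a preset correlation of 0.01 between genes and with an estimated one, and with fry. They covered muscle genes, developmental regulators, signalling, cell cycle, chromatin, matrix, stress, immune and metabolic genes, and markers of 7 other cell types a myoblast culture could hold. Adjusted p-values of lists are over the 28 lists of a contrast. Also fixed then were the design, the alternatives and the rule for the genes named. The rule took the 10 largest changes in each direction among genes past the threshold whose 2 groups of arrays did not overlap (5 in the tamoxifen control and the interaction), the 3 smallest p in each direction where fewer than 5 passed, up to 4 members with the smallest p from each list described, and Msx1. The other immediate early genes named, and the remaining interaction genes, were named after their values were seen.

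The contrast steps were tested on simulated data with 200 changed genes among 5624. For Msx1-ER with against without tamoxifen, 22.7% of genes changed by 0.5 (log2), 70% of those changed by 1 and 93.6% of those changed by 2 were recovered, and 5.13% of the calls were false. For the interaction the shares were 7.31%, 40.3% and 80.5%. The groups share replicate numbers in the titles. Deviations from the group means were correlated between same-numbered arrays of the 2 Msx1-ER groups, at 0.13, 0.11 and 0.12, all above 0.1. The main fit held no replicate block, so its values for that comparison treat the arrays as unpaired. The count from a fit with the replicate number as a block, over all 4 groups, is therefore given beside it. Any pairing comes from this check of the values, since the labels state no shared day or batch.

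Alternatives were quantile normalization, centring on the median, adding 16 or 64 to the linear signal, no filter, a filter at 60%, the mean over a gene's probe sets, probe sets tested singly, moderation without a trend or robustly, array weights, fits on the compared arrays only, the replicate number as a block, and leaving out each array. Scan dates and hybridisation batches were not used here.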

Results

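Gene expression was measured in C2C12 cells, a mouse myoblast line, that carried a retrovirus encoding Msx1-ER or the same retrovirus without an insert. Msx1 is a homeodomain transcription factor of embryonic progenitor cells. Msx1-ER is its fusion to a tamoxifen-regulated part of the oestrogen receptor, so that adding tamoxifen is meant to switch the protein on. Cells of each kind received 0.2 nM tamoxifen or its solvent for 6 h, which gave 4 groups with 3 arrays each and 12 arrays in total. The labels call the replicates biological. Signals of 5624 genes on a single-colour oligonucleotide array were compared on the log2 scale. The number of arrays limits the precision, and an exact test of 3 against 3 arrays cannot go below p = 0.1.

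Rank correlations between arrays lay between 0.938 and 0.96 within groups and between 0.929 and 0.957 across groups. The first principal component, with 16.8% of the variance, placed the Msx1-ER arrays with tamoxifen at 14.7 to 19 and the other 9 arrays at -13.7 to 4.9. Replicate 2 of Msx1-ER with tamoxifen stood apart on the second component, at 21.8. The signal at the 10th percentile of an array averaged 3.5 and 3.47 (log2) in Msx1-ER without and with tamoxifen, against 3.79 and 3.68 in empty vector. The 3'-minus-5' difference of the actin control, a sign of RNA integrity, averaged 0.05 to 0.13 (log2) in the 4 groups.

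The probe set for Msx1 was not called in any comparison. Its log2 signal was 8.32 ± 0.07 in empty vector and 8.43 ± 0.11 in empty vector with tamoxifen (SD, n = 3 each). In Msx1-ER it was 8.30 ± 0.39 without and 8.60 ± 0.03 with tamoxifen (SD, n = 3 each). Msx1-ER minus empty vector was -0.02 without tamoxifen (limma adjusted p = 0.993, exact permutation p = 1, 2-sided) and 0.17 with it (limma adjusted p = 0.801, exact permutation p = 0.1). With tamoxifen the 3 Msx1-ER arrays (8.57 to 8.62) lay above the 3 empty-vector arrays (8.30 to 8.50). In this comparison 18.5% of all genes tested had no overlap of arrays, in either direction, where chance gives 10%. Where this probe set lies relative to the cloned part of Msx1 is not given in the sources used here, so it does not check the labels. The same holds for Esr1, the oestrogen receptor gene. Without tamoxifen, 2 of its 4 probe sets were lower in Msx1-ER than in empty vector, with no overlap of arrays, as for 14.8% of all genes tested. They stood at 14.83 ± 0.10 against 15.20 ± 0.16 and at 4.99 ± 0.86 against 6.76 ± 0.14 (log2 signal, SD, exact permutation p = 0.1 each). The former lay at the 100th percentile of mean signal over all arrays, the latter at the 36.6th, below the filter at 40%.

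In Msx1-ER cells, tamoxifen lowered Myf5, Cyp1b1, Ptgs2 and Has2 and raised Nppb and Ccnd1. Myf5, a transcription factor that commits cells to the muscle lineage, was lower with tamoxifen than without it, with a log2 change of -2.88 ± 0.42 (SE, n = 3 per group). Its signal with tamoxifen was dim and uneven (5.97 ± 1.20, SD), and the change was -3.28 to -1.97 over the alternatives, past the threshold in all. Cyp1b1, a cytochrome P450 enzyme, fell 4.67-fold, Ptgs2, the inducible prostaglandin synthase, 4.64-fold, and Has2, which makes hyaluronan, 4.46-fold. Nppb, which encodes B-type natriuretic peptide, rose 4.15-fold, from 8.87 ± 0.18 to 10.93 ± 0.20 (log2 signal, SD, n = 3). Of 5624 genes, 24 were higher and 28 lower in limma's test at an adjusted p of 0.05, and 25 of these 52 changed at least 2-fold, 5 upward and 20 downward.

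**Figure D1:**
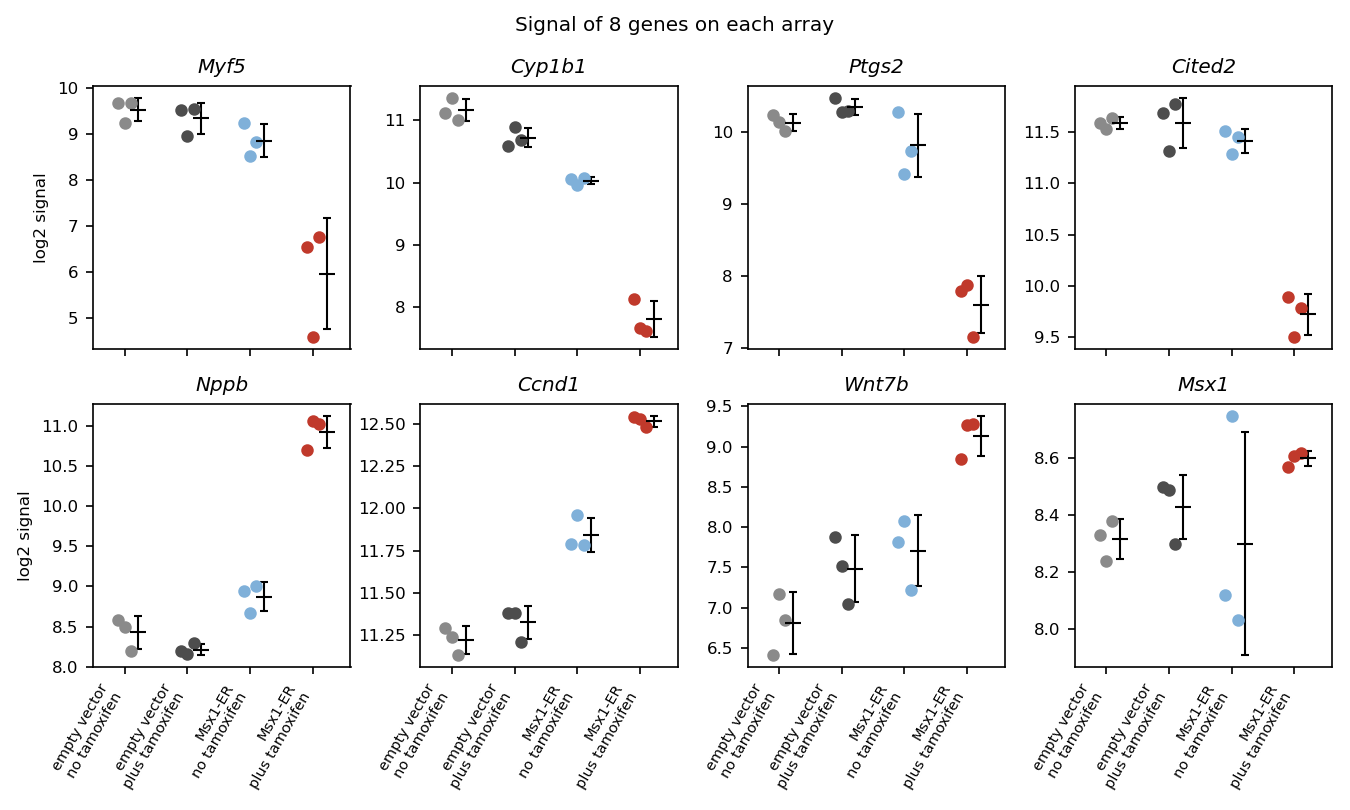
Log2 signal of 8 genes on each of the 12 arrays (vertical axis, a range of its own per gene) by group (horizontal axis), with 3 arrays per group as points and the mean ± SD as a black bar. Myf5 averaged 5.97 in Msx1-ER with tamoxifen and 8.85 to 9.52 in the other groups, while Msx1 averaged 8.30 to 8.60 in all 4 groups.

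After Myf5 (limma adjusted p = 0.00157), Cyp1b1 (1.31e-06), Ptgs2 (3.68e-05) and Has2 (0.000713) came Npr3, a natriuretic peptide receptor, at -2.03 ± 0.38 (log2, SE; -2.34 to -1.30 over the alternatives) and Vcam1, a cell adhesion molecule, at -1.73 ± 0.24. Vcam1 had 3 probe sets, and the dimmest of them went the other way, at 0.34, while the third gave -0.89. Cited2, a transcriptional co-regulator, fell by 1.69 on the log2 scale (limma adjusted p = 3.74e-06). The surface protein Cd200, the guidance factor Sema3a and the matrix protein Thbs2 changed by -1.61, -1.55 and -1.53. Thbs2 also had -0.80 with tamoxifen in empty vector, where it was not called (limma adjusted p = 0.659). Among the genes that rose, Nppb (limma adjusted p = 3.31e-06) was followed by the tubulin gene Tubb4a at 1.73 ± 0.34 and the Wnt ligand Wnt7b at 1.42 ± 0.29. The zinc finger gene Repin1 changed by 1.28 and Socs3, a feedback inhibitor of cytokine signalling, by 1.06. Adgrg1, Cebpb, Pgf, Btg2 and the homeobox gene Dlx3 rose by 0.82 to 0.97 (log2). Over 23 or 24 alternatives, the call was lost in 12 for Socs3, 11 for Pgf, 8 for Repin1, 7 for Wnt7b and for Adgrg1, 6 for Tubb4a, 5 for Npr3 and for Dlx3, and 1 for Sema3a. A second probe set of Repin1 gave 0.55. Without tamoxifen, Repin1 and Tubb4a averaged 6.68 and 6.48 (log2 signal) in Msx1-ER, below 7.69 and 7.89 in empty vector, differences not called. With tamoxifen they averaged 7.96 and 8.21 in Msx1-ER and 8.02 and 7.67 in empty vector. Their rises thus started from a low mean in Msx1-ER without tamoxifen.

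Of 13 measured myogenic regulators, Myf5 was lower and no member was higher over all genes tested. Adjusted over the list alone, 2 members were lower, Myf5 and Met, the receptor for hepatocyte growth factor. Met had a log2 change of -1.55 ± 0.35 (SE) and missed the threshold over all genes (limma adjusted p = 0.0513), as did Myod1 at -0.34 ± 0.15 (0.584). None of 29 contractile and differentiated muscle genes passed. Immediate early genes went both ways, with 3 of 28 higher (Btg2, Dusp1 and Gadd45b) and 3 lower (Ptgs2, Ccn2 and Sgk1). Adjusted over the list alone, 9 were higher and 5 lower. Dusp1, a phosphatase of MAP kinases, rose by 0.76 ± 0.12 (log2, SE), and Ccn2, a matricellular growth factor, fell by 0.72 ± 0.10. The call of Gadd45b was lost in 10 of 24 alternatives.

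In the BMP and TGF-beta list, Inhba, which encodes the activin A subunit, changed by -1.26 ± 0.16 and Id3, a BMP target, by -0.52 ± 0.11 (log2, SE), and none of the other 26 of 28 measured members passed. The call of Id3 was lost in 8 of 24 alternatives. In the Wnt list, Wnt7b was the 1 called gene of 22, and the list was higher as a set in limma's fry (adjusted p = 0.033) but not in camera (0.213). Adjusted over the list alone Wnt4 also passed, at 2.06 ± 0.53, but over all genes it did not (limma adjusted p = 0.1). Among 17 cyclins and CDK genes of G1, Ccnd1, the cyclin that drives entry into the cycle, rose by 0.67 ± 0.10 (limma adjusted p = 0.0013). Ccnd1 was also the 1 called gene of 13 oestrogen response genes. No member of the DNA replication (35 genes) or mitosis (37 genes) lists passed. Snai2, a repressor of epithelial genes, fell by 1.01 on the log2 scale.

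In limma's camera, heat shock genes were the 1 list of 28 tested that moved as a set, downward (limma camera adjusted p = 0.00673, median log2 change -0.17 over 17 genes). The call was lost with adjusted p = 0.117 with an estimated correlation (-0.019, below the preset 0.01). No difference of the list's response between the vectors was called (interaction, limma camera adjusted p = 0.338). Its 1 called member was Dnajb4, a co-chaperone, at -1.14 ± 0.21 (log2, SE; lost in 5 of 24 alternatives), and 2 members were lower adjusted over the list alone. Dnaja1 had -0.49, Hspa8 -0.38 and Hsph1 -0.29, none past the threshold over all genes.

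Same-numbered arrays of the 2 Msx1-ER groups deviated together, and a fit with the replicate number as a block called 79 genes, 38 higher and 41 lower, among them all 52. Leaving out replicate 3 of Msx1-ER without tamoxifen gave 30 genes, and replicate 2 or 3 with tamoxifen gave 31 or 29. The numbers higher and lower were 18 and 21, 11 and 24, and 10 and 20 without replicate 1, 2 and 3 of Msx1-ER without tamoxifen, and 8 and 27, 9 and 22, and 9 and 20 without replicate 1, 2 and 3 with tamoxifen. Limma without its intensity trend gave 31, array weights gave 85, and centring each array on its median gave 14 higher and 25 lower.

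Tamoxifen alone changed 1 gene in cells with empty vector. Slc35g3, a member of a solute carrier family, was lower with tamoxifen, from 8.35 ± 0.10 to 6.05 ± 0.38 (log2 signal, SD, n = 3; limma adjusted p = 0.0136), a change of -2.30 that was -2.51 to -1.58 over the alternatives. This comparison serves as the control for the drug itself. At an unadjusted p under 0.05 limma gave 298 genes, where 281 would be given by chance. None of the other genes with the smallest p in each direction passed over all genes tested. They were the chemokine gene Ccl2 at 0.67 ± 0.12 (limma adjusted p = 0.146), the noncoding RNA gene Norad at 0.63 ± 0.12 (0.217) and the homeobox gene Vax2 at 2.01 ± 0.44 (0.481) on the higher side, and Errfi1 at -0.54 ± 0.13 and Atp13a3 at -0.54 ± 0.13 (both 0.481) on the lower side (log2, SE).

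In limma's camera 0 of 28 lists moved as a set with either correlation, and 3 had an unadjusted p under 0.05. Of 13 oestrogen response genes, none passed over all genes or adjusted over the list alone, and their median log2 change was -0.04. Adjusted over the list alone, 2 of 20 NF-kB and chemokine genes were higher, 2 of 28 immediate early genes lower and 1 of 17 p53 targets lower. Slc35g3 was lost, leaving 0 genes, without replicate 1, 2 or 3 of empty vector without tamoxifen, without replicate 2 or 3 of empty vector with tamoxifen, under the stricter filter, and in a fit on these 6 arrays only. In simulated data for this comparison, 26.3% of genes changed by 0.5 (log2), 67.6% of those changed by 1 and 92.7% of those changed by 2 were recovered. Most changes of 0.5 would thus be missed.

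**Figure D2:**
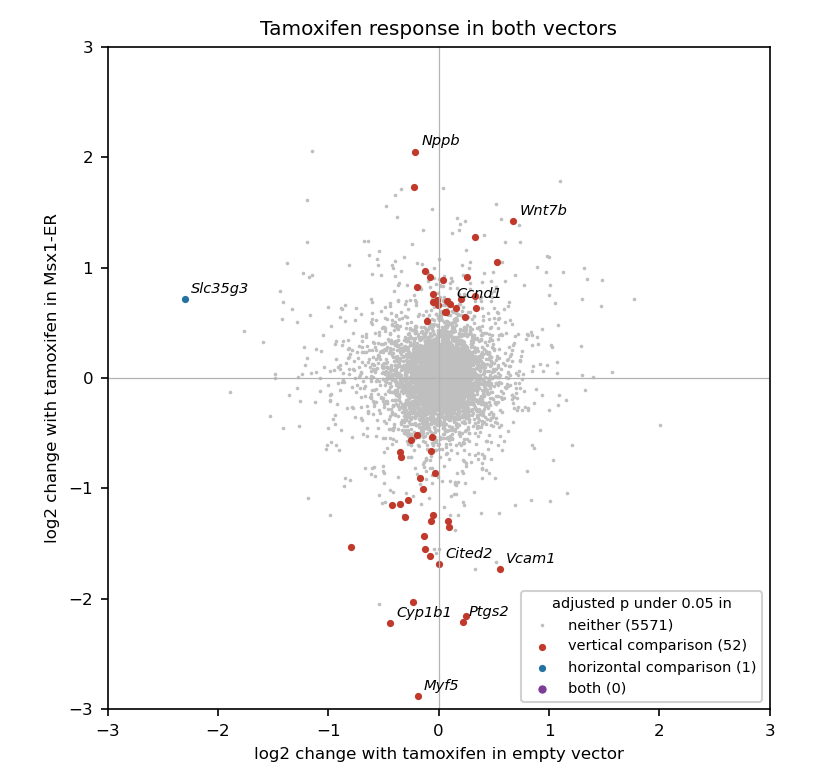
Log2 change of each of 5624 genes with tamoxifen in Msx1-ER (vertical axis) against that in empty vector (horizontal axis), coloured by the comparison in which the limma adjusted p was under 0.05. The 52 genes called in Msx1-ER spread along the vertical axis, and Slc35g3, at -2.30 on the horizontal axis, is the 1 gene called in empty vector.

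The responses to tamoxifen in the 2 vectors were set against each other gene by gene. Prostaglandin synthase Ptgs2, hyaluronan synthase Has2 and the adhesion gene Vcam1 responded more negatively in Msx1-ER than in empty vector, by -2.43 ± 0.30, -2.41 ± 0.39 and -2.29 ± 0.34 (log2, SE). For Vcam1 the alternatives gave -2.47 to -1.54, and its other probe sets gave 2.65, the opposite direction, and -0.79. Cyp1b1 and Cited2 differed by -1.79 ± 0.21 and -1.69 ± 0.19 in the same sense. Nppb responded more positively, by 2.27 ± 0.22, as did Slc35g3, by 3.01 ± 0.44 (2.09 to 3.30 over the alternatives), most of which came from its fall in empty vector. Errfi1, a feedback inhibitor of EGF receptor signalling, and Gadd45g, a growth arrest gene, differed by 0.94 ± 0.18 and 0.75 ± 0.14. Errfi1 changed by -0.54 in empty vector and 0.39 in Msx1-ER. Gadd45g went from 11.73 to 11.36 in empty vector and from 11.9 to 12.28 in Msx1-ER (mean log2 signal). Neither gene was called within either vector, so both differences came in part from an uncalled fall in empty vector. In limma's interaction test, 13 genes passed, 4 more positive and 9 more negative in Msx1-ER, with adjusted p from 0.000195 (Nppb) to 0.0468 (Errfi1). Over 23 alternatives the interaction call was lost in 16 for Cd200, 15 for Errfi1 and for Evi2a, and 12 for Gadd45g. It was lost in 11 for Bdnf, 10 for Pdk4 and 4 for Has2.

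Myf5 and Wnt4 did not pass the interaction test, at -2.69 ± 0.59 (limma adjusted p = 0.128) and 3.21 ± 0.75 (0.179). Myf5 was also not called in 19 of 23 alternatives and passed in the rest, and Wnt4 was not called in 22 of 22. In limma's camera 0 of 28 lists passed, and 7 had an unadjusted p under 0.05. Among 28 immediate early genes, Gadd45g was more positive and Ptgs2 more negative over all genes, and 5 in each direction passed adjusted over the list alone. Of the 52 genes called in Msx1-ER, 10 also passed the interaction test in the same direction and the others did not pass it, against 0.017 and 0.045 expected per direction from independent lists and at most 0 in 100 simulated unchanged data sets. The comparisons share the Msx1-ER arrays. The simulated value leaves out real changes and the independent lists leave out the shared arrays, so part of the excess over either may come from sharing them. Across genes, which are not independent replicates, the tamoxifen responses in the 2 vectors had Pearson r = 0.004, and 36 of the 52 genes (69.2%) had the same direction in empty vector, against 49.4% of all genes.

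Without replicate 1 or 3 of empty vector without tamoxifen the interaction count was 6 or 7, without replicate 3 of empty vector with tamoxifen 8, and without replicate 1, 2 or 3 of Msx1-ER without tamoxifen 6, 7 or 7. With any array left out, 2 to 3 genes were more positive and 4 to 8 more negative. The count was 6 in limma without the intensity trend and 8 with each array centred on its median.

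With tamoxifen in both, Msx1-ER cells differed from empty-vector cells in 114 genes, 64 higher and 50 lower. Myf5 was lower in Msx1-ER (9.33 ± 0.33 in empty vector and 5.97 ± 1.20 in Msx1-ER, log2 signal, SD, n = 3), by -3.36 ± 0.42 (log2, SE; -3.76 to -2.41 over the alternatives). Cyp1b1 was 7.53-fold, Ptgs2 6.70-fold and Has2 6.04-fold lower. Wnt4, a secreted Wnt ligand, was higher, from a dim 5.6 ± 0.28 to 8.76 ± 0.24 (log2 signal, SD), by 3.15 ± 0.53 (SE; limma adjusted p = 0.00337; 2.14 to 3.28 over the alternatives). Without tamoxifen Wnt4 averaged 6.75 ± 0.88 in empty vector and 6.7 ± 1.17 in Msx1-ER (log2 signal, SD). Part of its difference thus lay in a lower empty-vector mean with tamoxifen, a change not called. Nppb was 6.55-fold higher, and Synpo, an actin-associated protein, was higher by 2.28 ± 0.39 (log2, SE; 1.69 to 2.74 over the alternatives). Of the 114 genes, 44 differed at least 2-fold, 20 higher and 24 lower. This comparison sets the cells of the 2 vectors against each other when both have received the drug.

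Other genes with large differences were the neuropeptide gene Hcrt at 1.89 ± 0.41, Slc35g3 at 1.79 ± 0.31, the vitamin D receptor gene Vdr at 1.73 ± 0.32, Wnt7b at 1.64 ± 0.29 and the myelin protein gene Pmp22 at 1.59 ± 0.13 (log2, SE), all higher in Msx1-ER. The adhesion receptors Adgrg3 and Adgrg1 followed at 1.41 and 1.39. The empty-vector mean of Slc35g3 was 8.35 without tamoxifen and 6.05 with it (log2 signal). Its Msx1-ER mean with tamoxifen, 7.84, lay between these, so the difference came from the low empty-vector value with tamoxifen. Adgrg3 averaged 7.68 and 6.68 in empty vector without and with tamoxifen, a change not called, and 8.09 in Msx1-ER with it. Hcrt averaged 6.76 and 6.07 in empty vector without and with tamoxifen, and 7.72 and 7.96 in Msx1-ER. A difference in Hcrt, not called, thus stood without tamoxifen too. On the lower side, Npr3 had -2.31 ± 0.38, Cd200 -2.13 ± 0.20, Vcam1 -2.11 ± 0.24, the catenin gene Ctnna2 -1.99 ± 0.48, Cited2 -1.86 ± 0.13 and Sema3a -1.71 ± 0.26. Over the alternatives Hcrt ranged from 1.23 to 2.24, Slc35g3 from 1.17 to 2, Npr3 from -2.62 to -1.53 and Ctnna2 from -2.55 to -1.09. Other probe sets of Vcam1 gave 2.13 and -1.09, and dimmer ones of Ctnna2 gave -0.57 and -0.11. Over 23 alternatives the call was lost in 15 for Ctnna2, 5 for Hcrt, 4 for Adgrg3 and 1 for Vdr.

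Myogenic regulators were lower as a set (limma camera adjusted p = 0.0374, median log2 change -0.19 over 13 genes; adjusted p = 0.148 with an estimated correlation). Myf5 and Met passed over all genes, Met at -1.59 ± 0.35, and 1 higher and 5 lower members passed adjusted over the list alone. Six4 had -0.82 and Mef2a 0.67, neither past the threshold over all genes. Of 29 contractile and differentiated muscle genes, the sarcomeric actinin gene Actn3 was lower at -1.10 ± 0.18 and the skeletal actin gene Acta1 higher at 0.69 ± 0.14; adjusted over the list alone, 1 was higher and 2 lower. The calls of Met, Acta1 and Actn3 were lost in 4, 3 and 1 of 23 or 24 alternatives. A second, dimmer probe set of Actn3 gave -0.12.

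Cholesterol synthesis genes were higher as a set (limma camera adjusted p = 0.00307, median 0.24 over 21 genes; adjusted p = 0.113 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was the 1 called member at 0.72 ± 0.17 (lost in 10 of 24 alternatives), also adjusted over the list alone, and Msmo1, Sqle and Idi1 had 0.58, 0.46 and 0.42 without passing. Glycolysis and hypoxia genes were higher too (limma camera adjusted p = 0.0233, median 0.15 over 28 genes; adjusted p = 0.113 with an estimated correlation). Ndrg1 was the 1 called member at 0.39 ± 0.10 (lost in 15 of 24 alternatives), and adjusted over the list alone 3 were higher and 1 lower. Pfkp, a phosphofructokinase, had 0.80 and the hypoxia-induced repressor Bhlhe40 0.86, neither past the threshold.

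Growth and signalling genes went in both directions. Ccnd1 was 2.28-fold higher (log2 change 1.19 ± 0.10, SE) and Fgfr1, a receptor for fibroblast growth factors, 1.93-fold higher, whereas Myc, Phlda1 and Dusp6 of the same list, FGF and ERK signalling with 13 measured genes, were lower at -1.11, -0.79 and -0.69. Of 28 BMP and TGF-beta genes, Ltbp2 and Inhbb were higher at 1.06 and 0.64, and Inhba and Id3 lower at -0.94 and -0.44. Hes1, a Notch target, was higher at 0.62. Of 28 immediate early genes, 6 were higher and 5 lower, with Gadd45g at 0.92, Dusp1 at 1.06, Sgk1 at -1.47 and Ptgs2 at -2.74. In the extracellular matrix list of 41 genes, Col6a1 and Col6a3, both chains of type VI collagen, were higher at 0.97 and 0.52, and Lox, which cross-links collagen, and Col8a1 were lower at -0.94 and -1.07. The developmental transcription factors Dlx3 and Snai2 stood at 1.38 and -0.87. Over 23 or 24 alternatives the call was lost in 14 for Dusp6 and for Id3, 12 for Inhbb, 11 for Phlda1, 8 for Ltbp2, 5 for Hes1 and for Col8a1, 4 for Myc and for Col6a3, and 1 for Col6a1.

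Markers of cell types other than myoblasts gave 2 called genes. Pdgfrb, 1 of 4 measured genes of the fibroblast list, was higher at 1.19 ± 0.15 (log2, SE). Ogn, 1 of 2 in the bone and cartilage list, was lower at -1.33 ± 0.17. No marker passed among the 4 measured for adipocytes, 1 for endothelial cells, 1 for epithelial cells, 5 for neural cells and 7 for macrophages. So few measured markers leave the presence of such cells little tested. Of 52 genes called between tamoxifen and solvent in Msx1-ER, 44 were also called here in the same direction, against 0.27 and 0.25 expected per direction and at most 0 in 100 simulated unchanged data sets. Both comparisons use the Msx1-ER arrays with tamoxifen; the simulated value leaves out real changes and the independent lists leave out the shared arrays, so part of the excess over either may come from those arrays.

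Leaving out replicate 1 of empty vector with tamoxifen gave 74 genes, 45 higher and 29 lower, and leaving out replicate 1 or 3 of Msx1-ER with tamoxifen gave 73, 34 higher and 39 lower, or 71, 41 higher and 30 lower; array weights gave 175, and centring each array on its median gave 70 higher and 33 lower. The myogenic list was lost without replicate 1 of empty vector without tamoxifen (adjusted p = 0.0591 in limma's camera), replicate 2 or 3 of empty vector with tamoxifen (0.0689 or 0.162) or replicate 1 of Msx1-ER with tamoxifen (0.107), and the glycolysis list without replicate 1 of empty vector with tamoxifen (0.0523) or replicate 1 or 3 of Msx1-ER with tamoxifen (0.0886 or 0.0611).

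Without tamoxifen, 7 genes already differed between Msx1-ER and empty vector. The chemokine genes Ccl2 and Ccl7 were 2.83-fold and 2.22-fold higher in Msx1-ER (Ccl2 9.46 ± 0.16 in empty vector and 10.96 ± 0.14 in Msx1-ER, Ccl7 8.03 ± 0.08 and 9.18 ± 0.14, log2 signal, SD, n = 3). Pmp22 was 2.08-fold and Ccnd1 1.54-fold higher, and Col6a1 was higher by 0.65 ± 0.10 (log2, SE; 0.611 to 1.35 over the alternatives). Mcpt8, a mast cell protease gene, was 3.29-fold lower (from 8.42 ± 0.11 to 6.71 ± 0.45, log2 signal, SD), and Cyp1b1 2.18-fold lower (from 11.16 ± 0.18 to 10.03 ± 0.05). The comparison sets the cells of the 2 vectors against each other before induction.

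The smallest limma adjusted p was 1.22e-05, for Ccl2, and the largest 0.0187, for Mcpt8, whose other probe set gave -1.27. The calls of Col6a1, Ccnd1 and Mcpt8 were lost in 8, 6 and 6 of 23 or 24 alternatives. A dimmer probe set of Pmp22 gave -0.77 and one of Cyp1b1 gave 1.08, both opposite to the brighter probe sets used. Myf5 had -0.67 ± 0.42 (limma adjusted p = 0.654). Contractile and differentiated muscle genes were lower as a set (limma camera adjusted p = 0.00955, median log2 change -0.22 over 29 genes; adjusted p = 0.231 with an estimated correlation). No difference of the list's response to tamoxifen between the vectors was called (interaction, limma camera adjusted p = 0.498). No member passed over all genes and 1 was lower adjusted over the list alone. Actn3 had -0.88 ± 0.18, Ankrd1, a cardiac ankyrin repeat protein, -0.41, the acetylcholine receptor subunit gene Chrna1 -0.44 and the myosin light chain gene Myl1 -0.56. A second, dimmer probe set of Actn3 gave -0.3. Of 20 NF-kB and chemokine genes, Ccl2 and Ccl7 were higher and none lower, both over all genes and adjusted over the list alone.

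**Figure D3:**
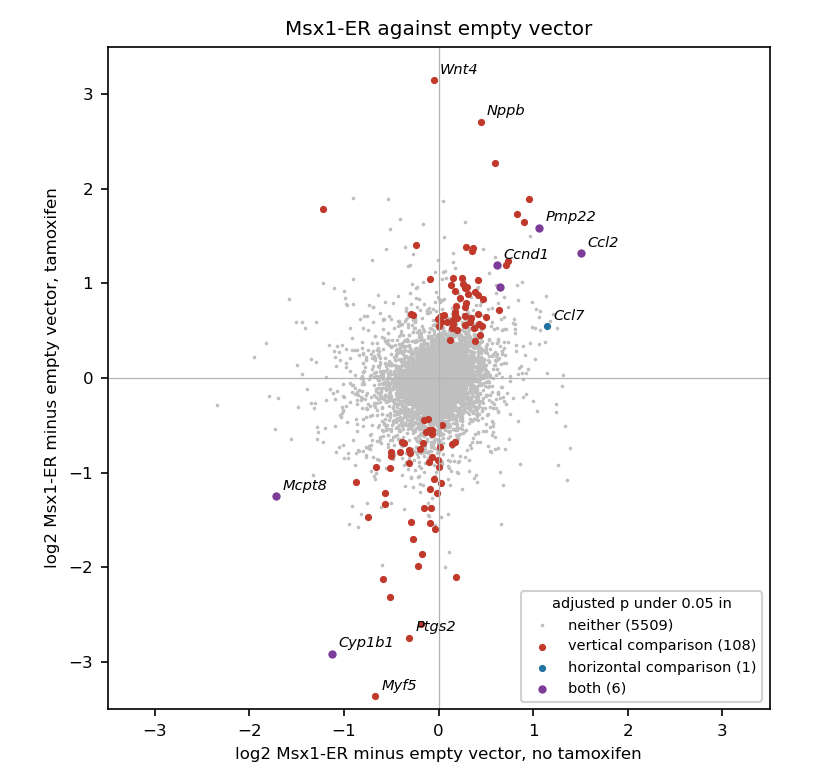
Log2 difference between Msx1-ER and empty vector for each of 5624 genes with tamoxifen (vertical axis) against that without tamoxifen (horizontal axis), coloured by the comparison in which the limma adjusted p was under 0.05. Ccl2, Ccnd1, Pmp22 and Cyp1b1 lie on the same side in both, while Myf5 and Wnt4 lie near -0.67 and -0.05 on the horizontal axis and at -3.36 and 3.15 on the vertical axis.

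The differences between the vectors with and without tamoxifen, which share no array, had Pearson r = 0.192 across genes, which are not independent replicates. It was 0.121 without replicate 1 of Msx1-ER with tamoxifen, 0.078 without a filter and 0.338 with the stricter filter. Of the 114 genes called with tamoxifen, 100 (87.7%) had the same direction without it, against 58.6% of all 5624 genes. Ccl2, Ccnd1, Col6a1, Pmp22, Cyp1b1 and Mcpt8 were called in both, 4 higher and 2 lower, against 0.057 and 0.018 expected from independent lists. Without replicate 2 of empty vector without tamoxifen 4 genes differed, and on the 6 arrays of this comparison alone also 4; quantile normalization gave 7 higher and 5 lower, and adding 16 or 64 to the linear signal gave 5 higher and 4 lower each. The muscle list was lost without replicate 2 of empty vector without tamoxifen (limma camera adjusted p = 0.077) or replicate 1 of Msx1-ER without tamoxifen (0.081).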

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

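Chosen only after the results were seen were the tests of residual activity, of separate infections, of handling, of swapped labels, of the position of the Msx1 probe set, of empty-vector arrays among those labelled Msx1-ER without tamoxifen, and of single wrong labels among the Msx1-ER arrays with tamoxifen; the other tests in this part were set beforehand.

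The response to tamoxifen differed between the vectors in limma's interaction test for 13 genes, listed here as the response in Msx1-ER minus that in empty vector (log2). Slc35g3 had 3.01 and Nppb 2.27. Ptgs2 had -2.43, Has2 -2.41, Vcam1 -2.29, Cyp1b1 -1.79 and Cited2 -1.69. Cd200 had -1.54, Evi2a -1.44, Pdk4 -1.39 and Bdnf -1.19, calls lost in 16, 15, 10 and 11 of 23 alternatives. Errfi1 had 0.94 and Gadd45g 0.75. Among 100 groupings of the arrays within each vector, the real one included, 8 gave at least 13 genes, the highest 35. By the share set beforehand, this count does not exclude chance. All 8 kept the real split of the Msx1-ER arrays or its mirror image, as 10 of the 100 did, and without that split the highest count was 2. Groupings with that split still hold the tamoxifen response of Msx1-ER, so their counts cannot decide about chance.

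Other splits of the 6 arrays were also counted for the comparisons of 2 groups, each with 10 splits, too few for a share under 0.05. The real split gave 52 genes for tamoxifen in Msx1-ER, the highest of the others 0, among them the 3 that also parted every same-numbered pair. For the vectors with tamoxifen the values were 114 and 3, without tamoxifen 7 and 0, and for tamoxifen in empty vector 1 and 1; the real split was the 1 split as large in the former 3, and 2 splits were as large in the last.

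Signal also changed in probe sets that no gene test used because they had no single gene name. Tested singly among 7453 probe sets, 5 of them were called for tamoxifen in Msx1-ER, all lower, and 14 between the vectors with tamoxifen.

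Of the 52 genes that tamoxifen changed in Msx1-ER, few of them called without tamoxifen, 41 (78.8%) had the same sign in Msx1-ER against empty vector without tamoxifen, with a median of 0.24 (log2) in the direction of induction, above 100% of 10000 random lists matched on expression and 0.18 to 0.27 with an array left out. The random lists held only genes not called, and genes are not independent replicates. Such lists may vary less than genes that change together. Both comparisons use the Msx1-ER arrays without tamoxifen with opposite sign, so chance in those arrays works against this pattern. Uneven brightness of the arrays is argued against by quantile normalization, after which the median was 0.23. Residual activity of the fusion protein without tamoxifen may account for it, but 0.24 is the pattern itself and no separate test of that activity was made. Separate infections could give differences without tamoxifen too, and since each vector may be 1 infection, infection and construct cannot be told apart here; that 5 of the 7 genes called without tamoxifen had the same sign at induction decides nothing.

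Immediate early genes changed in both directions with tamoxifen in Msx1-ER, with 3 called members lower and 3 higher. Stimulation by handling stays open, since the 3 members on the less frequent side are the pattern itself and test nothing. No single array made the pattern, since at least 2 members remained on the less frequent side without any 1 of the 12 arrays. A response to the fusion protein stays open as a hypothesis: of the 6 members, Ptgs2 alone passed limma's interaction test, and in empty vector tamoxifen gave 0 called of 28 members and 2 lower adjusted over the list alone.

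The Msx1 probe set was not called higher in cells labelled Msx1-ER, at -0.02 (log2) against empty vector without tamoxifen and 0.17 with it. With tamoxifen all 3 Msx1-ER arrays lay above the 3 empty-vector arrays, where 18.5% of all genes had no overlap in either direction. Of 4 Esr1 probe sets, 2 were lower in Msx1-ER without tamoxifen, with positions unknown too. Swapped vector labels are argued against by tamoxifen changing 52 genes in arrays labelled Msx1-ER and 1 in those labelled empty vector. A nearest-centroid rule on 100 genes, fitted without each array in turn, gave 10 of 12 arrays to their own vector, among them 3 of 3 Msx1-ER arrays with tamoxifen, but replicates 1 and 3 of Msx1-ER without tamoxifen to empty vector, which had been set beforehand to count for a wrong label. Those 2 being empty-vector arrays is argued against by a score over 87 genes called on the arrays with tamoxifen alone, 0.26 at the lowest in Msx1-ER without tamoxifen against a prediction limit of 0.24 from empty vector, a narrow margin; the rule had set this group against a mean that also held the tamoxifen arrays (1.08 to 1.17 on the score). A probe set outside the cloned part of Msx1 would give -0.02 too, and no value used here decides it.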

How the results depend on the processing

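All alternatives here were set before the data were examined. Of 37 named genes called for tamoxifen in Msx1-ER, 20 passed under every alternative, of 52 between the vectors with tamoxifen 30, of 7 without tamoxifen 4, of 13 in the interaction 6, and of 1 in empty vector 0; none of them changed direction. Signal over background limits the size of changes in dim groups: with 64 added to the linear signal, Myf5 changed by -1.97 with tamoxifen in Msx1-ER in place of -2.88.

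Counts of genes for tamoxifen in Msx1-ER were 31 without the intensity trend, 85 with array weights and 79 with the replicate block, and 29 to 55 with an array left out. Between the vectors with tamoxifen they were 175 with array weights and 174 with the replicate block, and 71 to 123. The interaction gave 8 with median centring, 6 without the trend, and 6 to 11. Between the vectors without tamoxifen the counts were 12 after quantile normalization, 4 on the compared arrays only, and 4 to 10. In empty vector they were 0 with the filter at 60% and on the compared arrays only, and 0 to 1. Fewer genes or arrays enter some of these fits by construction; otherwise the cause was not tested. Same-numbered arrays correlated at 0.01 to 0.12 in the other comparisons, and 9 of 12 arrays correlated best with their own number. With the block 12 of the 13 interaction genes remained, without Evi2a, and every gene called in the other comparisons stayed called.

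Msx1 without tamoxifen, not called, turned from -0.02 to 0.0411 after quantile normalization and 0.0845 after median centring, and to 0.02, 0.08 and 0.12 without replicate 3 of empty vector and replicates 1 and 3 of Msx1-ER, in a range of -0.24 to 0.12. Left-out arrays gave 0.17 to 0.52 for tamoxifen in Msx1-ER and 0.10 to 0.20 between the vectors with tamoxifen. The correlation of the vector differences was 0.247 with 64 added, 0.078 without a filter and 0.338 with the filter at 60%, and 0.121 to 0.236 with an array left out. That of the tamoxifen responses was 0.036 with array weights, and -0.044 to 0.057.

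With an estimated correlation 0 lists passed in any comparison (adjusted p in limma's camera 0.117 for heat shock, 0.148 for myogenic regulators, 0.113 for cholesterol synthesis and for glycolysis and hypoxia, 0.231 for contractile muscle). The estimates for heat shock, myogenic regulators and glycolysis and hypoxia were -0.019, -0.004 and -0.012, below the preset 0.01. A higher correlation between genes thus does not account for the loss of these lists. For cholesterol synthesis and contractile muscle the estimates were above it, at 0.023 and 0.059. For tamoxifen in Msx1-ER 3 lists passed with the filter at 60% and 2 with fry (heat shock and Wnt signalling), and 1 to 2 with an array left out. In the interaction 1 passed with the filter at 60%. Between the vectors with tamoxifen 1 passed after quantile normalization and 1 without a filter, and 1 to 5. Without tamoxifen 3 passed with median centring, 4 without a filter, 2 with the filter at 60%, 3 with array weights and 0 with fry, and 0 to 3. Myogenic regulators had adjusted p = 0.0622 after quantile normalization, 0.107 without a filter, 0.0757 without the trend, 0.129 with array weights and 0.0516 on the compared arrays only, and 0.00694 to 0.162 with an array left out. Glycolysis and hypoxia had 0.0622 after quantile normalization and 0.107 without a filter, and 0.0147 to 0.0886. Contractile muscle had 0.0637 with fry, and 0.00165 to 0.081. Heat shock had 0.00271 to 0.0452 and cholesterol synthesis 0.00152 to 0.0337.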

Other observations

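Both tests in this part were planned after the called genes had been seen, on members not among those seen.

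Several lists held no called gene in the comparisons that changed most. Of 15 Hox genes, 19 Polycomb genes and 13 genes of the nuclear envelope and linker histones, none passed for tamoxifen in Msx1-ER or between the vectors with tamoxifen. The same held for 45 genes of oxidative phosphorylation, 24 of ribosomal proteins and 42 of splicing factors. Of 32 genes of the unfolded protein and amino acid stress response, Cebpb, a transcription factor also induced by other stimuli, was the 1 called in each of these comparisons, at 0.92 ± 0.12 and 0.96 ± 0.12 (log2, SE). B2m, a subunit of class I histocompatibility proteins, was the 1 of 14 interferon response genes called between the vectors with tamoxifen, at 0.56 ± 0.14 (lost in 11 of 24 alternatives). None of 16 Notch genes passed for tamoxifen in Msx1-ER, and none of 17 p53 targets in either comparison.

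Srxn1, which repairs oxidised peroxiredoxins, and Sqstm1, an autophagy receptor, rose with tamoxifen in Msx1-ER by 0.64 and 0.52 (log2) and were higher than in empty vector with tamoxifen by 0.75 and 0.66; each of the former calls was lost in 12 of 24 alternatives. Both are known targets of NRF2, a regulator of antioxidant genes, and higher NRF2 target expression may go with the construct. Among 19 other targets that had not been seen, 14 had a positive difference between the vectors with tamoxifen and the median was 0.14, above 99.4% of 10000 random lists matched on expression. None of the 19 was called, and as a set they did not pass 0.05 in limma's camera.

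Ccn2, Thbs2 and Inhba, known targets of YAP and TAZ, fell with tamoxifen in Msx1-ER, and lower YAP and TAZ target expression was a candidate explanation. None of them passed the interaction test. Thbs2 changed by -1.53 in Msx1-ER and by -0.80 with tamoxifen in empty vector (log2), the latter not called (limma adjusted p = 0.659). Among 10 targets that had not been seen, 5 had a positive change and the median was -0.04, above 27.6% of random lists, so that the unseen members leave the idea open without bearing it out. Gadd45b, a target on the same list, rose.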
